A study of Mus musculus with 8 samples.

How the data were processed

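The study measured polyadenylated RNA of the basilar membrane, the sheet of the cochlea that carries the hair cells and their supporting cells, in mice at postnatal day 6. Per the labels' protocols, 1 µg of total RNA per sample went into a stranded mRNA library preparation. The 8 samples form 2 groups of 4, taken from the sample titles: hete and homo. The genotype tag calls the hete samples wild type and the homo samples a conditional knockout of Dnajc17, so the labels leave open whether the control animals carry a mutant allele, and the groups are called hete and homo here. Neither the driver of the deletion nor the deleted part of the gene is given in the sources used here. The labels number the libraries 1 to 4 in each group without saying that each came from a separate animal, so p-values measure the spread between these libraries, which may be technical.

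The expression table holds TPM (transcripts per 1000000, a unit scaled by transcript length and library) that the authors deposited for 78317 genes, rounded to 2 decimals, with the values of every library adding up to 1000000 within 1. Fastp, HISAT2, StringTie, RSEM, DESeq2 and the genome build GRCm39 are named, without versions or roles, per the submitters' processing notes. A second deposited table gives event numbers of alternative splicing per event type for the whole comparison, with no per-library values; its caller and threshold are not given in the sources used here. Another deposited table gives the authors' gene ontology enrichment with a p-value and adjusted p-value per term. TPM keeps no record of sequencing depth, so the depth of each library is unknown here, and no interval or detection limit that needs read numbers was computed. A value of 0 is given as listed at 0, because it may be a failed estimate.

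The design, fixed before the data were examined, named a test on read counts and, for tables in TPM, limma-trend. The second applied: log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3, with the trend and robust options of eBayes, all 8 libraries and genotype as the only term. Genes with a mean of at least 1 TPM over the 8 libraries were tested, 17811 in number, of which 14103 are protein-coding. A Benjamini-Hochberg adjusted p under 0.05 counted as changed. Fold changes are homo over hete on the log2(TPM + 1) scale, which understates changes of genes with low values. The same steps were tested on simulated data with 17811 genes and 4 libraries per group: the fit recovered 31.3% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 86.4% of those changed 4-fold, with 5 unchanged genes among 130 calls. The simulation planted 67, 67 and 66 genes of these sizes and drew noise independently for each gene. With fewer changed genes the adjusted cut is stricter, so recovery in the data may be lower.

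Before the data were examined, 29 gene lists with 500 distinct members were fixed, covering cell types of the cochlea and of tissue around it, splicing, stress and cell cycle; 459 members were tested. Each list was tested with camera at its preset correlation of 0.01, two-sided, with adjustment over the 29 lists, then with camera and an estimated correlation, and with fry. The genes named are Dnajc17, up to 10 called genes in each direction that have a gene name and no overlap between groups, and the list members with the smallest p: 4 for each list called by camera and 2 for each other list, where the rule fixed beforehand allowed up to 4 for all and the lower number was chosen after the list calls were seen. The rule left out unnamed gene models and pseudogenes. Any gene outside it is said to be chosen after its values were seen. Some genes that the rule names are not reported here.

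Chromosomes and gene order came from the GENCODE M21 annotation, which is on GRCm38, matched by Ensembl gene ID for 16371 of the 17811 tested genes. Since the authors' build is GRCm39, no coordinates are printed. Pseudogene transcripts were matched to protein-coding transcripts of the same annotation with blastn 2.17.0 at an E-value limit of 1e-20. The alternatives were another normalization, other filters on low values, a pseudocount of 0.1 in place of 1, the replicate number as a block, a fold threshold, and each library left out in turn. A rescaling over protein-coding nuclear genes, eBayes without the robust option and a run without genes on chromosome 2 were added after the data were seen. Tests on read counts were left out, because TPM values are not counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.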

Results

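Gene expression was measured in the basilar membrane of mice at postnatal day 6, in 4 hete and 4 homo libraries of a Dnajc17 conditional knockout. Dnajc17 encodes a J-domain protein with an RNA recognition motif, and the study's title concerns RNA splicing in auditory hair cells and hearing. Between 28159 and 28969 genes had a TPM above 0 in each library. Transcripts encoded in mitochondria made up 8.69 to 10.4% of the TPM of a library, and mt-Atp8, a subunit of the mitochondrial ATP synthase, was the highest gene in all 8. The mitochondrial share was 9.70% ± 0.50 (SD, n = 4) in hete and 9.38% ± 0.61 (SD, n = 4) in homo (two-sided exact permutation test, p = 0.429). Shares of protein-coding transcripts (p = 0.914) and of pseudogenes (p = 0.857) and the number of genes above 0 (p = 0.771) also differed by less than the spread between libraries in the same exact permutation test, without adjustment over the 4 measures. The first principal component held 16.9% of the variance and the second 16.5%, and hete and homo libraries overlapped on both.

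Dnajc17 (ENSMUSG00000034278, chromosome 2), the targeted gene, was not lower in the homo libraries. Its TPM was 26.51, 25.45, 25.09 and 22.06 in hete replicates 1 to 4, and 29.33, 27.65, 31.08 and 18.04 in homo replicates 1 to 4. The log2 fold change was 0.07 (SE 0.15, 95% interval -0.27 to 0.41; limma-trend, adjusted p = 0.969). A gene-level value from the whole tissue does not show whether an exon is missing from the transcripts of a few cells, so this value does not check the labels. Without homo replicate 3 the log2 fold change was -0.01.

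The comparison of homo with hete asks which transcripts of the basilar membrane change when Dnajc17 is deleted. Metap1d (ENSMUSG00000041921, chromosome 2), which encodes a mitochondrial methionine aminopeptidase, rose from 31.1 ± 1.5 to 50.4 ± 2.94 TPM (SD, n = 4 each; log2 fold change 0.68, SE 0.07; limma-trend, adjusted p = 0.0146), and all 4 homo values lay above all 4 hete values. Gm4353 (ENSMUSG00000091900, chromosome 7), a processed pseudogene named after its values were seen, fell: it had 7.84, 10.03, 11.6 and 10.28 TPM in the hete libraries, 0.36 in homo replicate 1, and was listed at 0 in the other homo libraries (adjusted p = 4.24e-05). The best match of the Gm4353 transcript among protein-coding genes was Nup35, a nuclear pore protein on chromosome 2, with 99.6% identity, so reads of the 2 genes may not be separable. These were the only 2 of the 17811 tested genes that changed by limma-trend, 1 up and 1 down. At an unadjusted p under 0.05 there were 1078 genes, 634 higher and 444 lower. The groups did not overlap for 711 genes, 3.99% of those tested, where chance gives 2.86%. The absolute log2 fold change had a median of 0.09 and was under 0.5 for 95.8% of tested genes. The signed log2 fold change had a median of 0.02 over all tested genes, so small medians of the lists below are to be read against 0.02 and not 0. The call of Metap1d ended without hete replicate 1 (adjusted p = 0.0574), hete replicate 2 (0.055), homo replicate 2 (0.11) or homo replicate 3 (0.0948), and with no filter on low values (0.0544), in a range of 0.00706 to 0.11 over the filters, scalings, pseudocounts and left-out libraries.

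**Figure D1:**
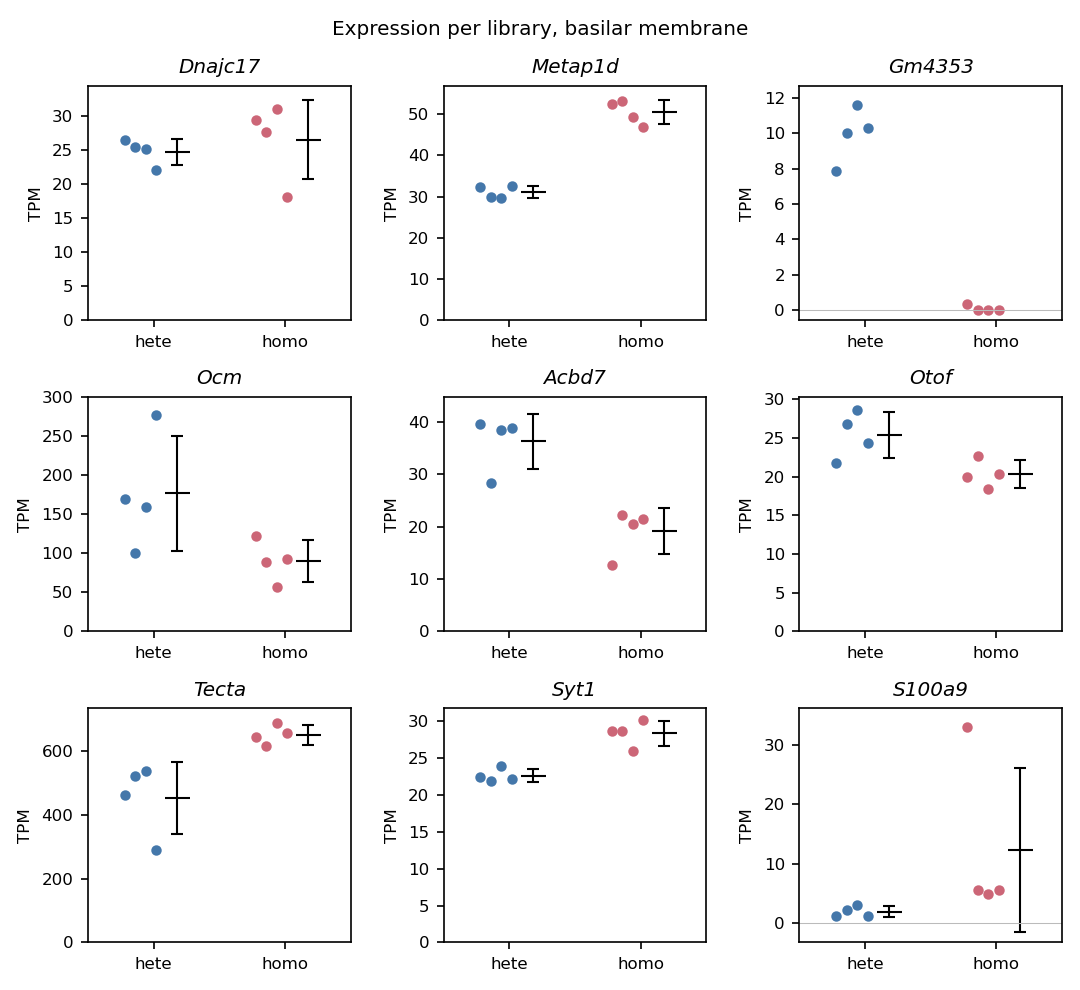
Expression in TPM of 9 genes in each of the 4 hete (blue) and 4 homo (red) libraries; black bars are the mean and the SD, left out for Gm4353, which was listed at 0 in 3 homo libraries. Metap1d lies at 29.71 to 32.48 in hete and at 46.83 to 53.22 in homo, while the Dnajc17 values of the groups overlap.

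Transcripts of hair cells, the sensory cells of the cochlea, were lower in homo as a group by camera. The hair cell list means per library overlapped, at 3.70 to 4.04 in hete and 3.55 to 3.80 in homo on the log2(TPM + 1) scale. In a two-sided exact permutation test of the list mean, without adjustment over lists, p was 0.229. The same test gave 0.171 for inner hair cell markers, which also overlapped, and 0.0286 for outer hair cell markers, which did not. Of 24 tested hair cell markers, 17 were lower and 7 higher, with a median log2 fold change of -0.10 (camera adjusted p = 0.00514, adjusted p = 0.572 with an estimated correlation). All 7 tested outer hair cell markers were lower (median -0.17, camera adjusted p = 0.00885, adjusted p = 0.572 with an estimated correlation), as were 3 of 5 inner hair cell markers (median -0.15, camera adjusted p = 0.0439, adjusted p = 0.572 with an estimated correlation). The largest difference was in Ocm, the calcium buffer oncomodulin of outer hair cells, with 177 ± 73.7 TPM in hete and 90.2 ± 26.4 in homo (SD, n = 4 each; log2 fold change -0.92, SE 0.34; adjusted p = 0.76). Otof, the calcium sensor of the hair cell synapse, stood at 25.3 ± 2.98 and 20.3 ± 1.76 TPM (-0.30, SE 0.10), and Atp2a3, a calcium pump, at 11.5 ± 2.72 and 8.01 ± 1.31 (-0.46, SE 0.17). The outer hair cell genes Chrna10, a subunit of the efferent acetylcholine receptor, and Strc, which encodes stereocilin, had log2 fold changes of -0.25 (SE 0.12) and -0.21 (SE 0.15). The inner hair cell genes Slc17a8, the vesicular glutamate transporter, and Slc7a14 had -0.15 (SE 0.16) and 0.05 (SE 0.14). Acbd7, with 36.3 ± 5.28 TPM in hete and 19.2 ± 4.35 in homo (-0.90, SE 0.17), was the 1 hair cell marker that changed when adjusted over the list alone, and it lies on chromosome 2. No member of these 3 lists changed over all genes tested. The calls of all 3 lists ended without hete replicate 4, with an adjusted p of 0.10 and a median of -0.02 for hair cell markers, 0.193 and -0.01 for outer and 0.193 and -0.13 for inner hair cell markers. That of hair cell markers also ended without homo replicate 3 (0.0667, median -0.05). That of inner hair cell markers ended without hete replicate 2 (0.0666), hete replicate 3 (0.104, median -0.08), homo replicate 1 (0.116), homo replicate 2 (0.0515) or homo replicate 3 (0.175, median -0.05). Without hete replicate 1 the medians were -0.15 for hair cell and -0.26 for inner hair cell markers, and without homo replicate 4 that of outer hair cell markers was -0.11. With no filter on low values the outer median was -0.08, and with at least 5 TPM in 4 libraries the inner median was -0.30.

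Genes of the hair bundle, the mechanosensory organelle, and of the hair cell synapse followed the same direction by camera. Their list means per library overlapped between groups (exact permutation test of the list mean, p = 0.2 for the bundle and 0.171 for the synapse list). These lists are not separate evidence, as they share members with the hair cell lists. Otof, Chrna9 and Chrna10 are shared with the synapse list, and Espn and Tmc1 with the bundle list. Of 34 hair bundle and mechanotransduction genes, 23 were lower (median -0.07, camera adjusted p = 0.0223, adjusted p = 0.572 with an estimated correlation). Cib2, a subunit of the transduction complex, had 50.1 ± 3.69 TPM in hete and 41.4 ± 1.89 in homo (SD, n = 4 each; log2 fold change -0.27, SE 0.07; adjusted p = 0.619). Tomt, needed to bring transduction channels to the bundle, and Myo15a, a motor that elongates stereocilia, had -0.35 (SE 0.11) and -0.38 (SE 0.14), while Pls1, an actin-bundling plastin, stood higher at 0.24 (SE 0.09). Of 16 synapse and ion channel genes, 12 were lower (median -0.13, camera adjusted p = 0.00514, adjusted p = 0.572 with an estimated correlation). They include Cabp2, a calcium-binding protein of the synapse (-0.51, SE 0.20), and Chrna9, a subunit of the efferent receptor (-0.37, SE 0.13). No gene of either list changed over all genes or adjusted over the list alone. Without hete replicate 4 the adjusted p was 0.121 for the bundle list (median -0.02) and 0.0756 for the synapse list (median -0.08). The bundle call also ended without hete replicate 3 (0.0635, median -0.04) or homo replicate 1 (0.146, median -0.04) and with no filter on low values (0.0662). The medians were -0.11 and -0.21 without hete replicate 1, and that of the synapse list was -0.08 without homo replicate 3.

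Markers of supporting cells and of spiral ganglion neurons were higher in homo as groups by camera. The neuron list means per library overlapped widely, at 3.46 to 4.29 in hete and 3.75 to 4.54 in homo on the log2(TPM + 1) scale. Of 20 supporting cell markers, 16 were higher (median 0.06, camera adjusted p = 0.0223, adjusted p = 0.572 with an estimated correlation). The members with the smallest p encode the tectorial membrane proteins Tecta, at 453 ± 113 TPM in hete and 650.5 ± 29.9 in homo (SD, n = 4 each; log2 fold change 0.56, SE 0.18; adjusted p = 0.687), Tectb (0.21, SE 0.07) and Otog (0.28, SE 0.07), followed by the transcription factor Prox1 (0.26, SE 0.13). For Tecta, Tectb and Otog all 4 homo values lay above all 4 hete values. Hete replicate 4 held the lowest Tecta value (290.87 TPM, 462.83 to 537.51 in the other hete libraries), and without it the log2 fold change was 0.36. Of 18 neuron markers, 17 were higher (median 0.15, camera adjusted p = 0.0223, adjusted p = 0.703 with an estimated correlation). Syt1, a calcium sensor of synaptic vesicles, stood at 22.6 ± 0.91 and 28.4 ± 1.73 TPM (0.31, SE 0.07), Isl1 at 0.29 (SE 0.08), Ntrk3 at 0.43 (SE 0.19) and Gap43 at 0.30 (SE 0.14). Syt1 and Isl1 changed when adjusted over the list alone, and no gene of either list did over all genes tested. Markers of Schwann and satellite glia, which surround these neurons, were higher for 15 of 16 members (median 0.13, camera adjusted p = 0.194), with Egr2 at 0.62 (SE 0.26) and Foxd3 at 0.36 (SE 0.22). The neuron call ended without hete replicate 1 (adjusted p = 0.456, median 0.03), hete replicate 4 (0.222), homo replicate 2 (0.0515) or homo replicate 4 (0.763, median 0.01). Its median was 0.27, 0.25 and 0.33 without hete replicate 2, hete replicate 3 and homo replicate 3. The supporting cell call ended without hete replicate 2 (0.10), homo replicate 1 (0.103) or homo replicate 4 (0.116). Its median was 0.02, 0.10, 0.11 and 0.10 without hete replicates 1, 3 and 4 and homo replicate 3. Ntrk3 was at 0.25 without homo replicate 4.

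Granulocyte and interferon genes were higher in homo as groups by camera. Of 10 listed granulocyte markers, 4 passed the filter on low values, and all 4 were higher (median 1.07, camera adjusted p = 0.00514, adjusted p = 0.572 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, had 1.19, 2.25, 3.05 and 1.29 TPM in hete replicates 1 to 4 and 33.1, 5.67, 4.94 and 5.67 in homo (log2 fold change 1.77, SE 0.57; adjusted p = 0.727). Its partner S100a8 (0.95, SE 0.41) and the neutrophil granule genes Ngp (1.20, SE 0.43) and Camp (0.28, SE 0.32) had means of 0.33 to 2.28 TPM in hete. Ngp, at 0.33 TPM in hete and 2.59 in homo, passed the filter through its homo values. Adjustment over the list alone covered only the 4 members that passed the filter, and Ngp and S100a9 changed in it. As Ngp was kept by its homo values, its change there is not separate support. All 16 interferon response genes were higher (median 0.23, camera adjusted p = 0.00514, adjusted p = 0.572 with an estimated correlation). Oasl2 stood at 0.51 (SE 0.21), Mx2 at 0.70 (SE 0.37), Isg15 at 0.59 (SE 0.32) and the RNA sensor Ifih1, on chromosome 2, at 0.22 (SE 0.11). None changed when adjusted over the list alone. No gene of either list changed over all genes tested. Without homo replicate 1 the granulocyte median was 0.61 over 3 genes, Ngp no longer passing the filter (0.68 over the same 4), and the adjusted p was 0.0266. With no filter on low values, which tests all 10, they were 0.23 and 0.0190, and with a pseudocount of 0.1 they were 1.67 and 0.00467. Without homo replicate 1 the log2 fold change was 1.17 for S100a9, 0.76 for Ngp, 0.61 for S100a8 and 0.02 for Camp. The interferon call ended without homo replicate 2 (0.170, median 0.09), where Mx2 stood at 0.46 and Isg15 at 0.28.

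Spliceosome components and cell cycle genes were slightly higher in homo as groups by camera. Of 57 spliceosome components, 41 were higher (median 0.05, camera adjusted p = 0.0228, adjusted p = 0.660 with an estimated correlation). Aqr, an RNA helicase of the spliceosome, had 22.2 ± 0.97 TPM in hete and 28.1 ± 1.15 in homo (SD, n = 4 each; log2 fold change 0.33, SE 0.07; adjusted p = 0.429) and changed when adjusted over the list alone. Snrnp200, another helicase, had 0.17 (SE 0.05), Sf3b1 0.16 (SE 0.06) and Dhx38 0.13 (SE 0.07). Aqr and Snrnp200 lie on chromosome 2. Aqr is also 1 of the 14 genes with a small p among the 201 tested genes centred on Dnajc17, described below. Of 45 splicing regulators, 33 were higher (median 0.06, camera adjusted p = 0.0704), but the members with the smallest p were lower. Clk1, a kinase of splicing factors, had 237 ± 9.91 TPM in hete and 174 ± 19.1 in homo (-0.45, SE 0.08; adjusted p = 0.284), and Tra2a, a splicing activator, had -0.23 (SE 0.07). Clk1 changed when adjusted over the list alone. Of 19 cell cycle genes, 17 were higher (median 0.14, camera adjusted p = 0.00514, adjusted p = 0.572 with an estimated correlation). Its members with the smallest p were the replication helicase subunits Mcm6 (0.30, SE 0.12), Mcm2 (0.26, SE 0.12), Mcm5 (0.29, SE 0.14) and Mcm3 (0.26, SE 0.12). None changed when adjusted over the list alone. No gene of these 3 lists changed over all genes tested. Without hete replicate 4 the adjusted p was 0.743 for the spliceosome (median 0.03) and 0.238 for the cell cycle list. The spliceosome call also ended without homo replicate 2 (0.151) or homo replicate 3 (0.0749) and with quantile normalization (0.0998, median 0.03). Without hete replicate 1 the spliceosome median was 0.04.

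The other lists were not called by camera, and none of their members changed over all genes or adjusted over the list alone. Among stress and death programs, p53 targets (16 tested, median 0.03, mean -0.02, camera adjusted p = 0.582) included Psrc1 at -0.27 (SE 0.19) and Sesn2 at -0.17 (SE 0.13). Apoptosis machinery (17 tested, median 0.05, adjusted p = 0.359) included Bcl2 at 0.14 (SE 0.08) and Bad at -0.16 (SE 0.09). Heat shock chaperones (15 tested, median -0.04, adjusted p = 0.241) included Dnajb1 at -0.15 (SE 0.10) and Hspa1a at -0.19 (SE 0.14). The unfolded protein and integrated stress response (17 tested, median 0.01, adjusted p = 0.957) included Asns, an asparagine synthetase, at 0.39 (SE 0.13) and Psat1 at 0.11 (SE 0.08). Notch pathway genes (17 tested, median 0.02, adjusted p = 0.771) included the ligand Jag1, on chromosome 2, at 0.24 (SE 0.07) and Hey2 at 0.18 (SE 0.08). Immediate early genes (12 tested, median 0.08, adjusted p = 0.0871) included Nr4a1 at 0.36 (SE 0.10) and Egr1 at 0.39 (SE 0.15). Stria vascularis and melanocyte markers (15 tested, median -0.07, adjusted p = 0.0642) included the potassium channel genes Kcnq1 at -0.20 (SE 0.11) and Kcne1 at -0.19 (SE 0.11). Macrophage markers (19 tested, median -0.03, mean 0.01, adjusted p = 0.771) included Aif1 at -0.30 (SE 0.11) and Fcer1g at 0.30 (SE 0.16).

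Among markers of tissue next to the basilar membrane, erythroid genes were lower for all 6 tested members (median -0.16, camera adjusted p = 0.164), with the globin genes Hbb-bs at 1676 ± 450 TPM in hete and 1416 ± 162 in homo (SD, n = 4 each) and Hbb-bt at a log2 fold change of -0.21 (SE 0.18). Mesenchyme and fibrocyte markers (14 tested, median 0.02, adjusted p = 0.827) included Postn at 0.17 (SE 0.10) and Tbx18 at 0.08 (SE 0.06). Endothelial markers (11 tested, median -0.00, adjusted p = 0.682) included Vwf at -0.30 (SE 0.17) and Egfl7 at 0.16 (SE 0.14). Bone markers (11 tested, median -0.02, adjusted p = 0.771) included Runx2 at 0.14 (SE 0.28) and Acp5 at -0.19 (SE 0.63). Cartilage markers (5 tested, median -0.07, mean 0.01, adjusted p = 0.598) included the abundant Col2a1 at -0.12 (SE 0.08) and Hapln1 at 0.18 (SE 0.19). Skeletal muscle markers were higher for all 4 tested members (median 0.29, adjusted p = 0.484), with Tnni2 at 0.38 (SE 0.26) and Mylpf at 0.33 (SE 0.33). Mitochondrially encoded genes (13 tested, median 0.03, mean -0.07, adjusted p = 0.510) included mt-Nd3 at -0.26 (SE 0.14) and mt-Atp6 at -0.15 (SE 0.09). Of 8 tested neighbours of Dnajc17, 6 were higher (median 0.01, mean -0.01, adjusted p = 0.884), with Gchfr at -0.46 (SE 0.24). The direction of camera followed the mean, not the median, for p53 targets and mitochondrially encoded genes, and the median, not the mean, for macrophage markers, cartilage markers and neighbours of Dnajc17. Of the 29 lists, 11 were called by camera at its preset correlation, 6 up and 5 down, and 0 were called with an estimated correlation, by fry or by fry's mixed test, whose smallest adjusted p were 0.572, 0.562 and 0.507. For the 6 lists called up, the exact permutation test of the list mean, without adjustment, gave a p of 0.0286 for granulocyte markers. It gave 0.0857 for supporting cell, 0.114 for interferon, 0.114 for cell cycle, 0.171 for spliceosome and 0.514 for neuron lists.

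**Figure D2:**
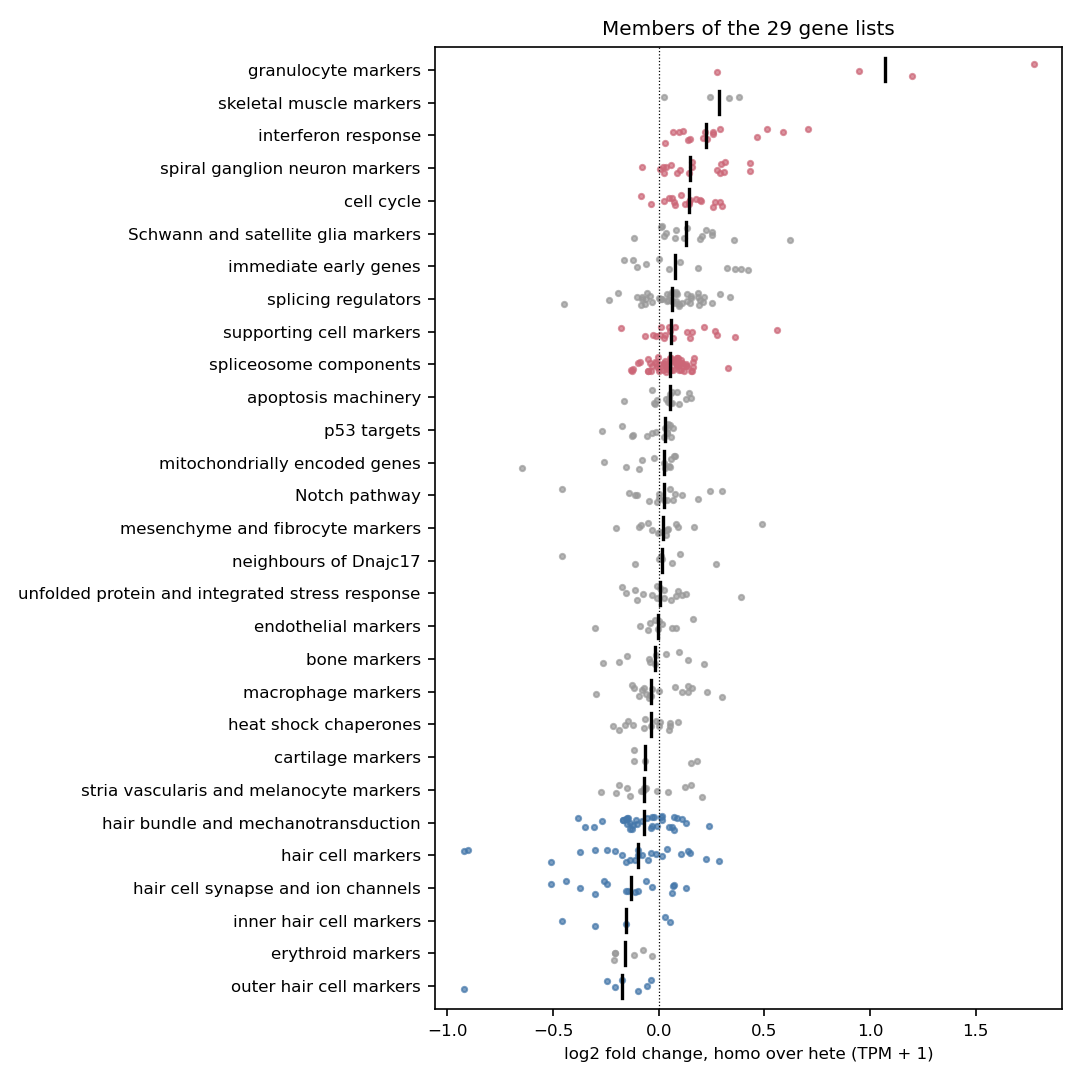
Log2 fold change, homo over hete, of every tested member (points) of the 29 gene lists, with the list median as a black bar; red lists were called higher and blue lists lower by camera at its preset correlation, and grey lists were not called. Medians run from -0.17 for outer hair cell markers to 1.07 for granulocyte markers.

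Genes with small p were concentrated on chromosome 2, which carries Dnajc17; this tally was chosen after the values were seen. Chromosome 2 held 21 of the 100 genes with the smallest p that have a chromosome in the annotation, and 7.81% of tested genes. Of the 201 tested genes centred on Dnajc17, 14 had an unadjusted p under 0.01 (6.97%), against 188 of 15065 genes on the other autosomes and X (1.25%; Fisher's exact test, two-sided, odds ratio 5.92, 95% interval 3.12 to 10.4, p = 4.66e-07). Of these 14 genes, 10 were higher and 4 lower in homo, and none changed over all genes tested. They include Ivd, an enzyme of leucine breakdown, with 80.6 and 111 TPM on average (log2 fold change 0.47, SE 0.09), Haus2, a subunit of the augmin complex (0.57, SE 0.09), the translation initiation factor subunit Eif3j1 (0.55, SE 0.09), the phospholipase Pla2g4e (-1.12, SE 0.20) and Scg5, a neuroendocrine chaperone (-0.66, SE 0.13). On the rest of chromosome 2, 25 of 1078 genes had such a p (2.32%; odds ratio 1.88, 95% interval 1.18 to 2.88, p = 0.00537 in the same exact test). Genes are not independent replicates, so these p-values describe this set of libraries.

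**Figure D3:**
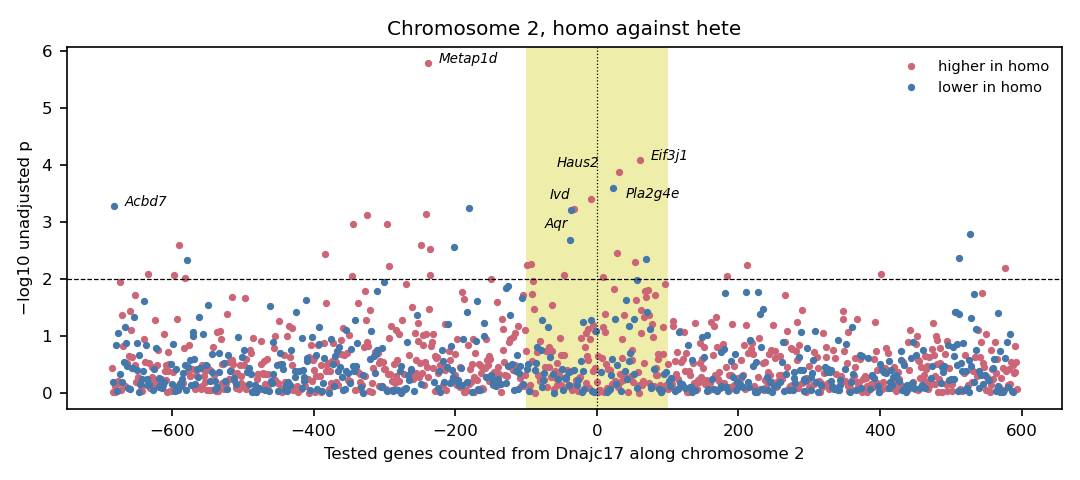
Unadjusted p, as -log10, of the 1279 tested genes of chromosome 2 in annotation order, counted from Dnajc17 (dotted line); red genes were higher and blue genes lower in homo, the dashed line is a p of 0.01 and the yellow band holds the 201 genes centred on Dnajc17. Metap1d lies 238 tested genes before Dnajc17, outside the band.

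The authors' deposited table of splicing events lists 3953 events for homo against hete, counted by either of 2 read sets called JC and JCEC, in the usual naming junction reads and junction plus exon reads. Skipped exons were the most frequent type in the authors' deposited table, with 2062 events, followed by retained introns with 767, alternative 3' splice sites with 452, alternative 5' splice sites with 337 and mutually exclusive exons with 335. Both read sets listed 3331 of the 3953 events in the authors' deposited table (84.3%). That share was 94.2% for alternative 3' splice sites, 89.0% for alternative 5' splice sites, 87.8% for skipped exons, 75.5% for mutually exclusive exons and 70.5% for retained introns, per the authors' deposited table. The table names no genes, direction or threshold, so whether these are detected events or events that differ between the groups is not given in the sources used here.

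**Figure D4:**
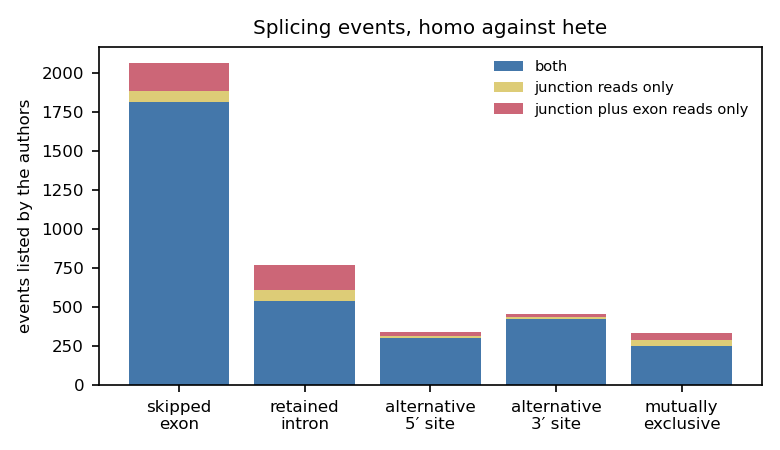
Number of splicing events of each type in the authors' deposited table, stacked by the read set that listed them: both, JC (junction reads) only, or JCEC (junction plus exon reads) only. Skipped exons make up 2062 of the 3953 events.

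The authors' deposited table of gene ontology terms lists 387 terms for a tested set of 142 genes, and 13 of them have an adjusted p under 0.05. Of these 13 terms in the authors' deposited table, those with the smallest p concern migration of myeloid cells and chemotaxis of leukocytes and neutrophils (adjusted p = 0.0286), with Cxcl10, S100a8, S100a9, Ccl21b and Ccl21e as members, and 6 of the 13 rest on 2 genes each. The chemokine genes Ccl21b and Ccl21e, near-identical copies, have the same value in every library, so their counts as separate members are uncertain: 1.42, 0, 3.65 and 1.8 TPM in hete and 4.21, 6.44, 5.3 and 6.8 in homo (limma-trend, log2 fold change 1.48, SE 0.41, adjusted p = 0.669). The authors' deposited table names 65 genes in its terms. Of these, 26 had a mean of at least 1 TPM, 15 of them higher and 11 lower in homo, and 1 changed by limma-trend; the other 39 were under 1 TPM and were not tested.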

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

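Both tests of the granulocyte list given here, that of erythroid genes and that of homo replicate 1, were chosen after the values had been seen. Of 164 groups of 4 libraries examined, 2 for each of 78 named genes and of 4 library measures, 10 held a library far from the others by Dixon's ratio at its 95% critical value, where chance gives about 8.2, so a single case carries little weight. Acbd7 was at 28.42 TPM in hete replicate 2, below 38.46 to 39.6 in the other hete libraries, and at 12.77 in homo replicate 1, below 20.41 to 22.17. Chrna9 was at 6.19 TPM in homo replicate 1, above 4.44 to 4.65 in the other homo libraries and within the hete range. Cib2 reached 55.66 TPM in hete replicate 3, above 48.04 to 48.46. Mx2 was at 3.1 TPM in hete replicate 3, above 0.83 to 0.93. Egfl7 was at 80.68 TPM in homo replicate 4, below 106.26 to 107.15. Clk1 reached 251.63 TPM in hete replicate 4, above 230.51 to 233.25. Mcm3 was at 16.76 TPM in homo replicate 2, above 14.16 to 14.35. Gm4353 was at 0.36 TPM in homo replicate 1 and listed at 0 in the other homo libraries. S100a9 was at 33.1 TPM in homo replicate 1, above 4.94 to 5.67, and 4 of the 10 cases are in that library.

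The higher granulocyte list invites the question whether a single library carries it. Against homo replicate 1 as the whole source, the median log2 fold change without that library was 0.606 over the 3 genes that then pass the filter, and 0.682 over the same 4 genes that gave 1.07 with it. The list means on the log2(TPM + 1) scale were 1.67 to 2.16 in homo replicates 2 to 4 and 1.15 to 1.42 in hete. More blood left in the homo samples would raise erythroid genes about as much as granulocyte genes. All 6 tested erythroid genes were lower, and their mean differed by -0.142 (95% Welch interval -0.726 to 0.443). The upper limit lies below the granulocyte medians of 0.606, 0.682 and 1.07, which rest on the 3 or 4 genes that passed the filter. It lies above the granulocyte median of 0.23 over all 10 listed genes with no filter on low values. The comparison therefore depends on the filter and does not decide on blood. The bound first written for excluding blood, an erythroid mean at or below 0, was met, and the rule was changed after this was seen. Set against 0, the interval leaves blood open. Granulocytes in the tissue or in blood richer in them, with or without a link to Dnajc17, remain possible and were not tested.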

How the results depend on the processing

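The rescaling over protein-coding nuclear genes, eBayes without the robust option and the run without chromosome 2 were chosen after seeing the data. The number of genes changed, 2 in limma-trend, was 1 with no filter on low values, with an absolute log2 fold change of at least 1, with the rescaling and without chromosome 2 (fewer genes tested in the last 2 of these), and 1 to 5 with a library left out: 5 without hete replicate 3, 4 without homo replicate 1 or 4, and 1 without hete replicate 1, homo replicate 2 or homo replicate 3. It was 2 or 3 in the other settings, the replicate block aside. The cause was not tested. Gm4353 stayed changed in every setting that tested it. The replicate number as a block gave 1 changed gene, losing Metap1d (adjusted p = 0.225), which the fold threshold and the run without chromosome 2 also leave out. The block called 11 lists, 10 of them also called without it: inner hair cell markers were lost (adjusted p = 0.0790) and stria vascularis and melanocyte markers gained (0.0374). Deviations of same-numbered libraries correlated at -0.084, -0.026, 0.049 and 0.0079, and only hete replicate 3 correlated best with its own number, so the labels share only a number. The DESeq2 Wald test, limma-voom and DESeq2 size factors were not run, since they need counts; quantile normalization took the place of the last, and limma-trend was itself the test used.

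Of the 29 lists, 11 were called by camera, and 5 to 12 with a library left out: 5 without hete replicate 4 (3 of them among the 11) and 7 without homo replicate 2. With an estimated correlation, or by fry, 0 were called. All 11 kept their direction in every alternative that tested them. The log2 fold change of Dnajc17 ran from -0.0136 to 0.237 with a library left out, changing sign without homo replicate 3, and from 0.04 to 0.07 otherwise. The log2 fold change moved by over 1.5 times or changed sign with at least 1 library left out for 37 of 78 named genes, most often without hete replicate 4 (19 genes). Among named genes other than Dnajc17 the sign changed for Runx2 without hete replicate 1 (range -0.0426 to 0.384 with a library left out), and for Slc7a14 (-0.0357 to 0.102) and Acp5 (-0.564 to 0.346) without homo replicate 4. None of the 3 was called. The 13 ontology terms in the authors' deposited table became 0 at an adjusted p under 0.01, the smallest being 0.0286. The authors' splicing totals stayed within 1.5 times of each other across read sets (3331 to 3953). Depth cannot be judged from TPM, so what it limits is unknown here.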

Other observations

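Chosen after the values had been seen were the tests of chromosome 2 (splits and windows), of the number of genes at an unadjusted p under 0.05, of even change among hair cell markers, of other tissue and of retained introns, and the genes of the next paragraph were picked in the same way. In the tests of even change, other tissue, intron number and retained introns, the outcome met the bound written for excluding the explanation. After this was seen, a margin beyond the spread was also asked for before excluding anything, so the first 3 are given as undecided here, where the bound alone would have excluded them. For retained introns the margin was later restated as the fall the idea needs. That was met, but the genes that set it had the largest falls of the list, so it carries little weight. For blood as a source of the granulocyte list, the written bound was likewise met and the rule changed afterwards, as described above.

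Eif3j1 and its paralog Eif3j2, subunits of a translation initiation factor, stood in opposite directions, neither passing the test over all genes. Eif3j1, on chromosome 2, had 10.96 ± 1.08 TPM in hete and 16.5 ± 0.72 in homo, and Eif3j2, on chromosome 18, had 27.3 ± 1.91 and 12.6 ± 3.71 (SD, n = 4 each; limma-trend, adjusted p = 0.160 and 0.143). Their sum was 38.3 ± 1.21 in hete and 29.1 ± 3.42 in homo; as the pair was picked by its values, no test of the sum is given. Nup35, the best match of Gm4353, lies on chromosome 2 and had 21.1 ± 1.71 TPM in hete and 25.8 ± 3.12 in homo (adjusted p = 0.746), with homo replicate 4 (21.26) inside the hete range. Rsrp1, an arginine- and serine-rich protein, was lower beside Clk1, at 297 ± 14.1 TPM in hete and 238 ± 6.26 in homo (SD, n = 4 each; log2 fold change -0.32, SE 0.06; adjusted p = 0.284).

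The number of genes changed could be chance: 10 of the 35 splits of the 8 libraries into 4 and 4 gave at least the 2 genes of the real split, and the highest other split gave 5. The same holds for the 1078 genes at an unadjusted p under 0.05, a number reached by 7 of the 35 splits, up to 1681. Chance was not excluded for the 11 lists called by camera either, since 3 of the 35 splits called as many and the highest other split also called 11.

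Chromosome 2 genes made up 21 of the 100 smallest p. Only 1 of the 35 splits, the real one, gave as many, and the highest other split gave 13. Since chromosome 2 was picked by its values, the fairer measure is the highest count on any chromosome, which reached 16 in other splits. The real split lay above all others on both measures, which argues against chance. That support is limited, as 1 of 35 is the smallest share possible. Of 73 other windows of 201 tested genes in the genome, the highest held 7 genes with p under 0.01, also on chromosome 2, against 14 around Dnajc17. A candidate explanation is that sequence or regulatory differences were carried along with the targeted allele. Hete and homo animals would then differ in the strain origin of this region. Loss of Dnajc17 acting on its neighbours is another. The list of its neighbours (8 tested) was not called by camera (adjusted p = 0.884) or by fry's mixed test (adjusted p = 0.534), and no member changed. That list is a small part of the 201 genes, so it does not decide, and the 2 explanations were not tested against each other. Reads shared with copies elsewhere might add to the small p on chromosome 2. Gm4353 lies on chromosome 7 and its match Nup35 had an unadjusted p of 0.0222 (limma-trend), so this pair does not add to them. Eif3j1 is among the 14 genes around Dnajc17, and its paralog Eif3j2 moved the other way. The test of pseudogenes does not cover that pair. Of pseudogenes off chromosome 2 with a p under 0.01, 1 of 11 had its best match on chromosome 2, against 22 of 416 others (Fisher's exact test, odds ratio 1.79, p = 0.46), which is too few to decide. Metap1d, Acbd7, Aqr, Snrnp200 and Jag1 lie on this chromosome, and without its genes 11 lists were still called, the same 11.

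The lower hair cell list could be chance, since 7 of the 35 splits gave a camera p as small as the real one (0.000512) and the smallest of the others was 1.51e-06. Fewer hair cells in homo would lower all markers alike; Cochran's Q of the 24 members was 65.8, above 53.7 in the highest other split, but without the 4 members on chromosome 2 it was 37.7 against 46.2, so uneven change rests on those members and fewer cells stay possible. Other tissue taken along in the dissection might dilute hair cells; 4 of 7 lists of other tissues had a mean log2 change under 0.05, none by more than its SE, so this is open. Lower transcript levels per hair cell after loss of Dnajc17 stay open and cannot be separated from cell number in whole tissue.

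Loss of a splicing factor might lower transcripts with many introns. Over 14008 protein-coding genes, Spearman's rho of the log2 fold change with intron number was 0.108, opposite in sign to that idea, while other splits reached 0.197 in absolute value, so the test decides nothing; genes are not independent replicates. A shared fall of transcripts known for retained introns, raised by Clk1 and Rsrp1, was looked for in 18 such genes without Clk1, Rsrp1 and Tra2a: their median log2 fold change was 0.0268, with all 18 between -0.11 and 0.13, and other splits reached 0.102 in absolute value. The 3 genes set aside had the largest falls of the 21 listed, the smallest being -0.23 for Tra2a. That the other 18 lie above it was therefore fixed beforehand and excludes nothing. Of these 18, 12 were higher in homo, so no shared fall was seen among them. A small one, or a change in these 3 alone, stays open.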
